A study of Homo sapiens with 12 samples.

How the data were processed

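RNA was sequenced from 12 libraries of human hepatocellular carcinoma lines. Hep3B and Huh7, both established lines grown from liver tumours, were each measured as parental cells and as lenvatinib-resistant cells, with 3 libraries per group. Lenvatinib is an oral inhibitor of the VEGF and FGF receptors, PDGFRA, KIT and RET. Total RNA was extracted with a spin-column kit and made into Illumina libraries, per the labels' protocols. The labels name DMSO or lenvatinib as the treatment without saying which libraries received which, so whether the drug was present at harvest is not known here. The labels do not say that the replicates were separate cultures, so every p-value measures the spread between these samples, which may be technical.

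The authors deposited 1 table per line, mapped to GRCh37 per the submitters' processing notes. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. In the deposited Hep3B table the signal values, one column per library, were found from the values themselves to be 2 times the square root of size-scaled reads, each entry tied to 1 RefSeq transcript. Undoing this gave whole reads for 100% of the values, within 0.05 of a whole number. The deposited Huh7 signal values are reads per Ensembl gene divided by 1 factor per library, and 100% of these also came out as whole reads within 0.05. Both deposited tables also give the authors' log2 fold change and an FDR-adjusted p-value, per the file headers, from a tool not given in the sources used here. The largest deposited adjusted p-value in the Huh7 table was 0.0499, so this table holds a selection of genes that had already passed a test, while the Hep3B table holds 4982 entries with a deposited adjusted p-value of 0.05 or more. The tables were normalized separately, and their levels are not compared with each other except where stated.

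The reads recovered per library, over listed genes only, ran from 6363939 to 7475190 in parental Hep3B, from 6184939 to 6884477 in resistant Hep3B, from 12029528 to 14174202 in parental Huh7 and from 11480608 to 11800771 in resistant Huh7. These totals leave out genes that the tables do not list. An entry of the Hep3B table holds only part of the reads of a gene with several transcripts. To show this, the level in each line was taken as the mean of its parental and resistant group means. The median log2 ratio of the Huh7 level to the Hep3B level was 0.14 over 1927 genes with 1 RefSeq transcript. It was 2.71 over 709 genes with 5 or more. Low Hep3B values of such genes may therefore understate their expression. Paralogs with nearly identical sequence, among them the GSTA, UGT1A, HLA, metallothionein and histone genes, and overlapping or antisense genes are uncertain where the counting could divide their reads. Of the 8718 Hep3B entries, 1 names no gene; it held 0.000119% of the reads and was left out. The Hep3B table has 7497 coding and 1220 non-coding transcripts, and the Huh7 table has 7533 genes. The reference gene table (GRCh38.p14) was used only for names, transcript numbers and which genes neighbour each other. It held the transcript of 8564 Hep3B entries and the Ensembl gene of 7516 Huh7 entries.

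Values below are scaled reads, meaning recovered reads divided by the deposited factor of the library. The plan fixed before the data were examined foresaw counts or a unit such as FPKM, and the files held neither. As planned for normalized values, limma 3.58.1 (trend and robust, in R 4.3.3) was run within each line on log2(scaled reads + 1), two-sided, for entries with at least 1 scaled read in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2 scale, resistant over parental, which understates changes of genes with few reads. The difference between lines was the difference of both log2 fold changes over its standard error, for the 3885 symbols in both tables. Overlaps of calls were set against the product of the lists with a one-sided Fisher exact test in each of 4 direction pairs. The 39 gene lists, holding 726 genes, were fixed before the data were examined, and cover lenvatinib's targets and their pathways, bypass receptors, transport, liver functions, cell state, stress, immune genes and other cell types. Of their genes, 357 were in the Hep3B table and 416 in the Huh7 table. Lists with at least 5 measured members were tested with limma's camera (preset correlation of 0.01) in Hep3B and, since the Huh7 table is a selection, with limma's fry in Huh7, adjusted over all lists and both lines. The fry test asks whether a list's genes move on balance one way and does not compare the list with other genes. Where a group had 0 reads, a fold is given as at least that against 3 reads over the group; with 1 to 3 reads, the ratio has its exact 95% counting interval. Intervals and floors cover counting error only.

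The genes named were chosen by a rule fixed before the data were examined. It takes, for each line, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and whose higher group had at least 5 CPM, clone names and pseudogenes left out. It also takes all measured lenvatinib target kinases and up to 4 called members of each list with the largest absolute change. Between the lines it takes the 5 largest common rises and falls, ranked by the smaller of the absolute changes in both lines. It also takes the 5 largest differences in each direction among genes called in opposite directions. CPM was counted over the listed genes. Alternatives, tried 1 at a time, were limma without trend, quantile normalization, median centring, other filters and a pseudocount of 0.1, a 2-fold minimum, the replicate number as a block, each library left out, all 12 libraries in 1 fit and the authors' deposited calls. Added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, genes with 1 RefSeq transcript, a mean of at least 100 scaled reads, the calls over shared symbols and the direction of list members in Huh7.

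The gene tests were first run on simulated reads with known changes. For Hep3B, limma recovered 58.2% of 1.5-fold, 71.6% of 2-fold and 84.8% of 4-fold changes over 8717 genes, and 5.30% of its calls were false. For Huh7 the shares were 85.1%, 89.6% and 100% over 7532 genes, with 2.66% false. For the difference between lines, 87.3% of 2-fold and 92.2% of 4-fold differences were recovered over 3885 genes, with 7.93% false. Most simulated genes had no change, whereas the real Huh7 genes had been selected for a change. The shares for Huh7 and for the difference therefore do not describe the real calls. In Hep3B limma made 151 calls on the simulated reads and 4317 on the real ones, so its shares may not carry over either. Libraries of 1 group differed by more than counting noise (chi-square per degree of freedom from 2.84 to 5.32 in Hep3B and from 2.50 to 13.4 in Huh7), so none was a copy of another. Between groups this ratio ran from 68.6 to 74.3 in Hep3B and from 106 to 138 in Huh7. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.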

Results

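Transcript levels were measured in 4 groups of 3 libraries: parental Hep3B, lenvatinib-resistant Hep3B, parental Huh7 and lenvatinib-resistant Huh7. The lines were compared each within its own table, 8717 transcripts in Hep3B and 7531 genes in Huh7, and then with each other over the 3885 gene symbols that both tables hold. The first principal component separated parental from resistant libraries in each line and carried 69.8% of the variance in Hep3B and 91.0% in Huh7. The Huh7 genes had been selected for a difference between these groups, which favours such a component. The shares of the lines are therefore not comparable. Levels are scaled reads, given as mean ± SD (n = 3 per group), and log2 fold changes are resistant over parental, given ± SE.

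The Hep3B comparison addresses which transcripts differ between resistant and parental cells of this line. Resistant Hep3B cells had far higher levels of some matrix genes. COL1A1, a chain of type I collagen, rose from 24.9 ± 7.23 to 1937 ± 177 scaled reads (log2 fold change 6.26 ± 0.16), and LOXL2, an enzyme that crosslinks collagen, rose from 11.8 ± 4.05 to 777 ± 42.3 (5.96 ± 0.19). Cyclin D1 (CCND1), which drives entry into the cell cycle, fell from 3938 ± 248 to 595 ± 51.7 (-2.73 ± 0.07). FGF19, the hormone that signals through FGFR4 and its co-receptor beta-Klotho, fell from 253 ± 7.52 to 56.2 ± 9.64 (-2.17 ± 0.15). Apolipoprotein B (APOB), the main protein of liver-made lipoproteins, fell from 119490 ± 13136 to 40799 ± 5420 (-1.55 ± 0.13).

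Among the largest rises in Hep3B were WNT11, a secreted Wnt ligand (6.04 ± 0.31), DIO3, which inactivates thyroid hormone (5.86 ± 0.41), MEGF6 (5.78 ± 0.73), the membrane protein gene EMP2 (5.43 ± 0.25) and SYT10, a synaptotagmin (5.34 ± 0.33). RTL1, an imprinted gene derived from a retrotransposon, had 2 reads over the parental libraries and 394 over the resistant ones, a ratio of 197 (counting interval 54.3 to 1635). The integrin subunit ITGB8 was 72.8-fold higher (24.6 to 356) and WIPF3 76.8-fold higher (25.9 to 375), each from 3 parental reads. Among the largest falls were PPP1R1A, a regulator of protein phosphatase 1, which was 82.9-fold lower (28.0 to 405), the potassium channel gene KCNJ5 (-5.19 ± 0.30) and the intestinal homeobox gene CDX2, 43.3-fold lower (14.5 to 213). CCDC141 was 45.3-fold lower (15.2 to 222). The ephrin receptor EPHA3 (-4.53 ± 0.53), TRABD2B (-4.22 ± 0.28), CRYBG1 (-4.19 ± 0.12), CHODL (-4.11 ± 0.25) and SRARP (-3.93 ± 0.37) fell too.

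Of the kinases that lenvatinib inhibits, 2 were measured in Hep3B. Each entry covers 1 transcript, of 5 RefSeq transcripts for PDGFRA and of 6 for FGFR3, and may not follow the whole gene. PDGFRA rose from 558 ± 33.0 to 915 ± 101 (0.71 ± 0.08, limma adjusted p = 3.97e-07). FGFR3 rose from 141 ± 34.9 to 205 ± 32.6 (0.56 ± 0.18, limma adjusted p = 0.0148), a call that 6 of its alternatives, median centring and the authors' deposited call among them, did not keep. Without parental replicate 2 the log2 fold change of FGFR3 was 0.33 (limma adjusted p = 0.059) and without resistant replicate 3 it was 0.44 (0.0728), so the size of this rise is uncertain. Of the 7 measured members of the FGF19 axis and FGF ligands, 3 rose, 2 fell and 2 did not pass, against 4 and 2 adjusted over the list alone. Beside FGF19, the beta-Klotho gene KLB fell (-0.50 ± 0.05), while FGF2 (0.93 ± 0.18) and FGF21 (1.51 ± 0.38) rose. The list as a whole did not pass (camera adjusted p = 0.718). Its median was 0.41 and its mean 0.01, and its test pointed down against the other genes.

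Output genes of the MAPK pathway moved apart in Hep3B. Of 16, 5 rose, 9 fell and 2 did not pass, against 5 and 10 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.157). The immediate-early genes FOS (16.1 ± 3.93 to 632 ± 6.97, 5.24 ± 0.17) and EGR1 (2.96 ± 0.08) and the phosphatase gene DUSP4 (1.40 ± 0.15) rose, whereas CCND1 fell. The median of the list was -0.51 and its mean 0.18. Angiogenic ligands also went both ways: PDGFB rose from 7.25 ± 1.72 to 141 ± 12.8 (4.12 ± 0.26) and VEGFC, a lymphangiogenic factor, fell from 329 ± 24.7 to 66.0 ± 3.51 (-2.30 ± 0.13), with 2 of 5 members higher, 1 lower and a camera adjusted p of 0.586.

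Secreted liver proteins and their regulators fell together in Hep3B. Of 19 measured, 14 fell, 1 rose and 4 did not pass, with the same 14 and 1 adjusted over the list alone (camera adjusted p = 1.58e-06, adjusted p = 0.0316 with an estimated correlation, range over its alternatives 1.9e-08 to 0.0316). The alpha-fetoprotein gene AFP (-1.15 ± 0.04) and APOH (5129 ± 178 to 2481 ± 14.2, -1.05 ± 0.05) were among those that fell beside APOB. Cholesterol synthesis genes fell, 9 of 13, with 1 higher and 3 not passing, against 10 and 1 adjusted over the list alone (camera adjusted p = 0.000671, adjusted p = 0.0502 with an estimated correlation, range 0.00026 to 0.0502). HSD17B7, a sterol synthesis enzyme (-0.76 ± 0.14), was among them. The entry of SREBF2, also lower, is a non-coding transcript with few reads and does not measure the sterol regulator's mRNA, and FDPS, another of the 9, lost its call under 12 alternatives, each of 5 single libraries left out among them (limma adjusted p from 0.06 without parental replicate 2 to 0.178 without resistant replicate 1), so the 9 overstate the falls. Fatty acid synthesis and storage genes fell, 7 of 10, with 1 higher and 2 not passing, against 7 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00214, adjusted p = 0.0809 with an estimated correlation, range 0.000114 to 0.0809). FASN, the fatty acid synthase (-1.20 ± 0.06), the desaturase genes FADS1 (-0.96 ± 0.05) and SCD (-0.93 ± 0.04) showed it. ER chaperones and unfolded protein response genes fell, 7 of 14, with 2 higher and 5 not passing, against 8 and 2 adjusted over the list alone (camera adjusted p = 0.0123). That call was lost with an estimated correlation (adjusted p = 0.0809 with an estimated correlation), with quantile normalization (0.139) and over genes with 1 RefSeq transcript (0.0735), the range over its alternatives being 0.000258 to 0.139. PDIA3 (-0.63 ± 0.04), SDF2L1 (-0.62 ± 0.08) and HSP90B1 (-0.56 ± 0.04) were lower.

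Other lists rose in Hep3B. Of 14 bile acid and xenobiotic metabolism genes, 8 rose, 2 fell and 4 did not pass, with the same 8 and 2 adjusted over the list alone (camera adjusted p = 0.0343, adjusted p = 0.117 with an estimated correlation, range 6.55e-05 to 0.117). Without resistant replicate 1 this adjusted p was 0.0518. The glucuronosyltransferase gene UGT2B15 (2.74 ± 0.44), the fetal cytochrome P450 gene CYP3A7 (2.48 ± 0.45) and the estrogen sulfotransferase gene SULT1E1 (42.7 ± 4.56 to 203 ± 7.70, 2.23 ± 0.16) rose, and UGT1A1 had 2 parental and 32 resistant reads, a ratio with a counting interval of 4.09 to 138. Of 5 apoptosis regulators, 4 rose, as they did adjusted over the list alone, and 1 did not pass (camera adjusted p = 0.00924, adjusted p = 0.0809 with an estimated correlation, range 5.15e-05 to 0.0809). Those that rose are killers of the BCL2 family: BIK (19.3 ± 0.588 to 112 ± 23.3, 2.46 ± 0.22), BOK (1.82 ± 0.08), BMF (1.42 ± 0.35) and BAK1 (0.32 ± 0.07), the last not with median centring. Of 8 Notch pathway genes, 4 rose, 1 fell and 3 did not pass, with the same 4 and 1 adjusted over the list alone (camera adjusted p = 0.0422, adjusted p = 0.312 with an estimated correlation, range 0.000273 to 0.312). Without parental replicate 3 this adjusted p was 0.0531. NOTCH3 rose from 339 ± 31.9 to 2473 ± 107 (2.87 ± 0.07), its target NRARP rose (2.04 ± 0.10), and so did NOTCH1 (1.11 ± 0.08) and HES1 (0.62 ± 0.06).

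The remaining Hep3B lists did not pass, with camera adjusted p-values from 0.0523 for TGF-beta targets to 0.904 for glycolysis and hypoxia. Single members changed strongly all the same. Of 18 extracellular matrix and integrin genes, 7 rose, 5 fell and 6 did not pass, as they did adjusted over the list alone (adjusted p = 0.464), the integrin subunit ITGA3 rising by 2.99 ± 0.18 beside COL1A1 and LOXL2. The YAP/TAZ targets CYR61 (1.58 ± 0.05) and CTGF (1.14 ± 0.05) rose in a list with 5 higher and 4 lower of 12 (6 and 4 adjusted over the list alone, adjusted p = 0.461). The TGF-beta-associated matrix gene LTBP2 rose (1.95 ± 0.07) and ID3 fell (-1.51 ± 0.08), in a list of 8 with 4 higher and 1 lower that passed with the replicate block (0.0299), with quantile normalization (0.00609), and without parental replicate 2 (0.0445) or resistant replicate 3 (0.0252), the range over its alternatives being 0.000499 to 0.186. The stem-cell factor SOX2 fell from 339 ± 33.5 to 33.3 ± 15.8 (-3.40 ± 0.26) and LIN28B fell by 1.85 ± 0.06, while SOX4 rose by 1.04 ± 0.05. Hexokinase 2 (HK2) fell from 6280 ± 94.2 to 1322 ± 65.4 (-2.25 ± 0.05) and the enolase gene ENO2 rose by 2.43 ± 0.14. The chemokine genes CXCL5 (-2.73 ± 0.07) and CXCL10 (-2.17 ± 0.33) fell. Of 16 mitotic genes, 4 rose, 5 fell and 7 did not pass (adjusted p = 0.586). Among cell-cycle genes that fell, NEK2 lost its call under 5 alternatives, CCNA2 under 2 and PLK1 under 1. Lists of NRF2, FGF19-axis, MAPK, urea cycle, Wnt, drug transporter, glycolysis and NF-kB genes had a median, a mean and a test direction that differed in sign. Of 4 measured fibroblast markers, COL1A1 and COL1A2 (2.03 ± 0.16) rose while LUM (-2.38 ± 0.14) and PDGFRB (-2.10 ± 0.17) fell, and of 2 leukocyte markers LYZ, which these cells already expressed, fell by 2.22 ± 0.12, while LAPTM5 rose from 1.96 ± 1.85 to 12.2 ± 7.58 (2.20 ± 0.70). The LAPTM5 call was lost with limma without trend and without parental replicate 3 (limma adjusted p = 0.0594), resistant replicate 2 (0.0874) or resistant replicate 3 (0.0722).

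Further Hep3B lists went both ways. Of 8 other receptor tyrosine kinases 2 rose, MERTK by 1.06 ± 0.12, and 4 fell, TYRO3 among them (-0.82 ± 0.06) (adjusted p = 0.271), and of 5 EGFR, MET and IGF ligand genes 3 rose, EREG by 1.05 ± 0.07 (adjusted p = 0.694). The other 2 rises were weak: HBEGF lost its call under 11 alternatives and AREG under 7, both without parental replicate 2 (limma adjusted p = 0.0551 and 0.0712) and with median centring. Of 10 drug transporters 2 rose, ABCC3 by 0.98 ± 0.11, and 4 fell (adjusted p = 0.586). Of 12 NRF2 targets 2 rose, AKR1C1 by 2.55 ± 0.41, and 6 fell, ABCC2 by 0.75 ± 0.08 (adjusted p = 0.0543, range 0.00245 to 0.444). That list passed with the replicate block (0.0414), and without parental replicate 2 (0.0456), resistant replicate 1 (0.0397) or resistant replicate 3 (0.0403). Of 9 fatty acid oxidation genes 3 rose, CPT1A by 1.53 ± 0.09, and 2 fell, FABP1 by 1.46 ± 0.14 (adjusted p = 0.647), and of 5 urea cycle genes 2 fell and 1 rose (adjusted p = 0.319). That rise, of TAT, was lost under 13 alternatives, with edgeR (0.0993), by the authors' call (0.345) and without parental replicate 2 (0.166) or 3 (0.157) or resistant replicate 2 (0.212) or 3 (0.0805) among them. Of 8 epithelial markers 3 rose, KRT7 by 2.39 ± 0.31, and 2 fell, KRT19 by 0.69 ± 0.04 (adjusted p = 0.728), and of 8 mesenchymal markers 3 rose, MMP14 by 0.72 ± 0.05, and 1 fell (adjusted p = 0.19). Of 10 Wnt targets 1 rose and 2 fell, DKK1 by 0.72 ± 0.05 (adjusted p = 0.586). Of 18 DNA replication genes 6 rose, E2F1 by 0.91 ± 0.07, and 2 fell (adjusted p = 0.517). Of 8 G1 regulators 1 rose and 2 fell (adjusted p = 0.348), and of 9 p53 targets 4 rose, GDF15 by 1.24 ± 0.06, and 1 fell (adjusted p = 0.472). Of 15 ATF4 targets 4 rose, PHGDH by 0.55 ± 0.05, and 2 fell (adjusted p = 0.683). Of 11 interferon-stimulated genes 6 rose, IRF9 by 0.75 ± 0.13, and 2 fell, USP18 by 1.14 ± 0.12 (adjusted p = 0.465), and of 11 histones 0 rose and 3 fell, 2 adjusted over the list alone (adjusted p = 0.391). Of these, HIST1H2BD and HIST2H2BE both lost their calls without parental replicate 1 (limma adjusted p = 0.108 and 0.0624) or resistant replicate 3 (0.130 and 0.0645), and HIST1H2BD also without parental replicate 3 (0.115) or resistant replicate 2 (0.110). Other counts of this paragraph hold weak calls too: under alternatives IFIT2 and PDK4 lost theirs 8 times each, SESN2 9 times, STC2 6, BBC3 5 and GRHL2 and TKT 4 each. NOTUM, the Wnt target that rose, lost its call 3 times. AKR1B10, the other NRF2 target that rose, had 3 parental and 30 resistant reads. Its call was lost without resistant replicate 1 (limma adjusted p = 0.0696) or 3 (0.0582). In lists too small to test, B2M fell by 0.73 ± 0.07 while HLA-B rose by 0.66 ± 0.13, MT2A rose by 1.09 ± 0.24 and ESAM by 1.06 ± 0.23.

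Over all 8717 Hep3B transcripts, limma called 2405 higher and 1912 lower in resistant cells, 931 and 411 of them by 2-fold or more, and 4400 did not pass. The groups did not overlap for 56.3% of transcripts, where chance gives 10%. The balance of rises and falls rested on the scaling: the deposited factors put the median log2 fold change at 0.07 with 55.7% of calls higher, and median centring put it at -0.09 with 1747 higher and 2704 lower (39.2% higher). By the authors' deposited calls, 1815 transcripts were higher and 1921 lower, and the 3646 called there and here had the same direction.

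**Figure D1:**
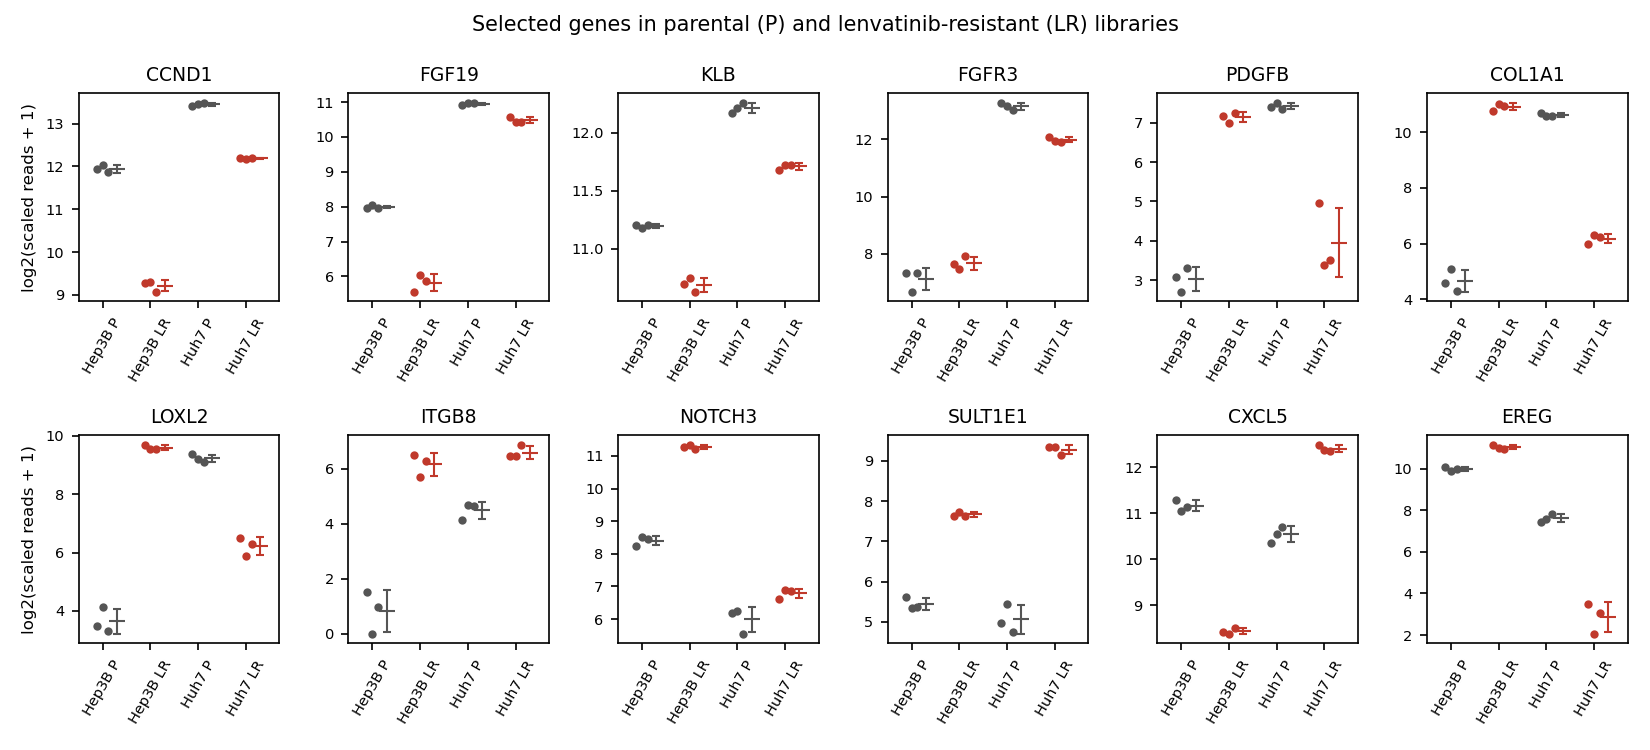
Log2(scaled reads + 1) of 12 genes in each library (points) with the mean and SD of the 3 libraries beside them, for parental (P, grey) and lenvatinib-resistant (LR, red) cells of both lines. The vertical axes differ between genes and do not start at 0; levels of the lines come from separately normalized tables. CCND1, FGF19 and KLB were lower in resistant cells of both lines, and COL1A1, LOXL2 and PDGFB went up in Hep3B and down in Huh7.

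The Huh7 comparison addresses the same question in the other line. It lies within genes that the authors had already selected for a low adjusted p, so every count is a count within that selection. The selection was made between the same groups, so small fry p-values come easily in Huh7 and lend little support to a list's direction. In resistant Huh7 cells OTC, a urea cycle enzyme, rose from 10.5 ± 1.81 to 316 ± 30.7 scaled reads (log2 fold change 4.79 ± 0.19), and SULT1E1 rose from 33.0 ± 8.74 to 623 ± 49.1 (4.23 ± 0.16). HAMP, which encodes the iron hormone hepcidin, fell from 1283 ± 177 to 18.0 ± 7.69 (-6.14 ± 0.20). COL1A1 fell from 1579 ± 72.4 to 71.7 ± 8.28 (-4.45 ± 0.10), and APBB1IP, an adaptor of integrin activation, went from 353 ± 4.47 to 0 reads, at least 340-fold lower.

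On the log2(scaled reads + 1) scale and among genes with at least 5 CPM, the largest rise in Huh7 was that of LCT, the lactase gene (3.77 ± 0.734 to 394 ± 41.9, 6.38 ± 0.22). RALYL (4.97 ± 0.41), CNTNAP2, a neuronal adhesion gene (4.38 ± 0.17), FJX1 (4.28 ± 0.39), the protease gene PRSS12 (3.96 ± 0.14), the stearoyl-CoA desaturase gene SCD5 (3.88 ± 0.26), APOD (3.81 ± 0.20) and EPDR1 (3.76 ± 0.36) followed. Several genes fell to a few reads or none. DPPA4, a gene of pluripotent cells, went from 217 ± 17.9 to 0 reads (at least 210-fold lower), CHM, a factor of Rab prenylation, from 93.4 ± 6.38 to 0 (at least 90.1-fold) and APOOL, a mitochondrial protein gene, from 84.2 ± 17.8 to 0 (at least 81.8-fold). DYNLT3, a dynein light chain, was 152-fold lower (counting interval 51.7 to 739) and ARHGAP23, from 281 reads to 1, was 257-fold lower with a lower bound of 45.7. KIRREL1 (-7.83 ± 0.37), the thrombin receptor family gene F2RL2 (-6.66 ± 0.31) and the adenosine deaminase gene ADA2 (-6.44 ± 0.33) fell as well.

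Of 4 lenvatinib target kinases measured in Huh7, 3 fell and 1 rose. FGFR3 fell by 1.17 ± 0.06 (limma adjusted p = 1.73e-12), FGFR1 by 0.44 ± 0.06 and FGFR4, the receptor for FGF19, by 0.24 ± 0.05, while PDGFRA rose by 0.48 ± 0.13 (limma adjusted p = 0.00194). All 5 measured members of the list of the FGF19 axis and FGF ligands fell (fry adjusted p = 8e-05), among them the ligand FGF18 (-1.82 ± 0.42), and of the axis KLB (-0.50 ± 0.05) and FGF19 itself (1979 ± 30.4 to 1428 ± 90.8, -0.47 ± 0.06). Of 16 MAPK output genes 13 fell and 3 rose (fry adjusted p = 9.32e-05), with CCND1 at -1.27 ± 0.05, IER3 at -1.34 ± 0.08 and FOSL1, a subunit of AP-1, at -0.91 ± 0.20. Of 12 other receptor tyrosine kinases 9 fell and 3 rose (fry adjusted p = 0.000109), with IGF1R at -1.06 ± 0.07 and EPHB2 at 1.92 ± 0.15. AXL fell from 13.6 ± 0.780 to 1.73 ± 1.18 (-2.50 ± 0.45). Of 6 EGFR, MET and IGF ligand genes 5 fell (fry adjusted p = 0.00115), EREG from 197 ± 27.0 to 6.91 ± 3.62 (-4.75 ± 0.30) and AREG (-0.40 ± 0.11). Of 8 angiogenic factors 7 fell (fry adjusted p = 5.8e-05), PDGFB from 171 ± 9.61 to 16.6 ± 11.7 (-3.48 ± 0.30) and PGF, the placental growth factor, by 1.28 ± 0.08.

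Matrix and mesenchymal genes were mostly lower in resistant Huh7 cells. Set against all listed Huh7 genes, the direction of the matrix, mesenchymal and epithelial lists did not pass (two-sided Fisher exact adjusted p = 0.376, 0.376 and 0.332). The TGF-beta and YAP/TAZ lists, at 0.0581 each, did not pass either. Of 19 extracellular matrix and integrin genes 13 fell and 6 rose (fry adjusted p = 5.15e-05), LOXL2 from 601 ± 52.5 to 75.1 ± 16.4 (-3.00 ± 0.14), while COL4A2 (3.44 ± 0.36) and LAMB3 (2.18 ± 0.29) rose. Of 13 TGF-beta targets 12 fell (fry adjusted p = 5.42e-05), with TGFBI at -1.54 ± 0.05 and TGFB1 at -1.49 ± 0.07, and of 18 YAP/TAZ targets 15 fell (fry adjusted p = 5.15e-05), with CYR61 at -1.79 ± 0.05. Of 9 mesenchymal markers 7 fell, the intermediate filament gene VIM by 1.38 ± 0.05 and LGALS1 by 3.26 ± 0.38 (fry adjusted p = 9.81e-05). Of 11 epithelial markers 8 rose and 3 fell (fry adjusted p = 0.000499), with the tight junction gene CLDN3 at 2.46 ± 0.19, the splicing regulator ESRP1 at 2.02 ± 0.13 and EPCAM at 1.13 ± 0.06. All 3 measured fibroblast markers fell.

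Of 11 bile acid and xenobiotic metabolism genes 10 rose (fry adjusted p = 3.46e-06), with the glutathione transferase genes GSTA2 (88.0 ± 10.1 to 1130 ± 59.7, 3.67 ± 0.10) and GSTA1 (2.62 ± 0.07). Of 12 fatty acid oxidation and PPARA targets 9 rose (fry adjusted p = 5.15e-05), among them PPARGC1A (1.72 ± 0.16), FABP1 (1.36 ± 0.07) and PPARA (1.20 ± 0.10). Of 8 urea cycle and amino acid genes 5 rose, ASS1 by 1.81 ± 0.07, and 3 fell, HPD among them (-2.31 ± 0.22) (fry adjusted p = 0.000113). Of 10 drug transporters 8 rose (fry adjusted p = 0.00112), the efflux pump gene ABCC2 by 1.26 ± 0.05, while ABCC1 fell by 0.86 ± 0.10. Of 17 NRF2 targets 11 rose (fry adjusted p = 0.000113), among them AKR1C1 (1.38 ± 0.05) and the cystine transporter gene SLC7A11 (1.24 ± 0.07). Secreted liver proteins were divided, 12 higher and 13 lower of 25 (fry adjusted p = 0.00567), with APOA2 at 1.43 ± 0.05 and AHSG at -1.28 ± 0.05. Cholesterol synthesis was divided too, 6 higher and 7 lower of 13 (fry adjusted p = 0.00692), with HMGCS1 at 0.77 ± 0.04, and its median was -0.15, its mean 0.09 and its test up.

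Of 12 ER chaperones and unfolded protein response genes 11 fell in Huh7 (fry adjusted p = 0.000566), SDF2L1 by 0.75 ± 0.10 and HYOU1 by 0.44 ± 0.05. All 7 metallothioneins fell (fry adjusted p = 0.00071), MT2A from 6274 ± 197 to 2190 ± 142 (-1.52 ± 0.06). Of 7 antigen presentation genes 6 fell (fry adjusted p = 0.00071), HLA-B by 1.67 ± 0.25 and HLA-C by 1.23 ± 0.12. All 7 replication-dependent histones rose (fry adjusted p = 9.81e-05), and 8 of 9 mitochondrially encoded genes rose, MT-ND6 by 0.62 ± 0.05 (fry adjusted p = 0.00505). The cell-cycle inhibitor gene CDKN1C fell by 2.74 ± 0.24 and CDKN1A rose by 0.66 ± 0.10. Of 10 mitotic genes 5 rose and 5 fell, and that list, the NF-kB targets and the Notch pathway did not pass (fry adjusted p = 0.391, 0.277 and 0.0543). The mitotic list passed with quantile normalization (0.033, range over its alternatives 0.033 to 0.954) and the Notch list with the replicate block (0.0103, range 0.0103 to 0.784).

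Other Huh7 lists were divided. Fatty acid synthesis and storage had 8 genes higher, ME1 by 1.29 ± 0.07, and 7 lower of 15 (fry adjusted p = 5.15e-05), and glycolysis and hypoxia 10 higher, EGLN3 by 3.63 ± 0.42, and 13 lower of 23, SLC2A3 at -3.83 ± 0.54 (fry adjusted p = 0.000411). Of 10 progenitor markers 7 rose, KLF4 by 1.75 ± 0.12 (fry adjusted p = 0.000499). Of 12 DNA replication genes 7 rose, MCM6 by 0.97 ± 0.05 (fry adjusted p = 0.001), of 8 G1 regulators 6 fell (fry adjusted p = 0.000411) and of 9 p53 targets 6 fell, GDF15 by 1.03 ± 0.07 (fry adjusted p = 0.000499). Apoptosis regulators were 4 higher, HRK by 2.26 ± 0.32, and 7 lower of 11, BAD at -1.05 ± 0.19 (fry adjusted p = 0.00112, range over alternatives 0.0032 to 0.220). Wnt targets were 5 higher, LEF1 by 3.05 ± 0.33, and 7 lower of 12, NOTUM at -2.84 ± 0.24 (fry adjusted p = 0.00505). Without parental replicate 1 the Wnt list gave 0.426 and without parental replicate 3 it gave 0.586. ATF4 targets were 10 higher, PCK2 by 1.24 ± 0.06, and 9 lower of 19 (fry adjusted p = 0.0203), and interferon-stimulated genes 7 higher, OAS1 by 1.65 ± 0.17, and 5 lower of 12, IFI35 at -2.35 ± 0.19 (fry adjusted p = 0.0203). The ATF4 call was lost with the replicate block (0.0595), without parental replicate 3 (0.0534), resistant replicate 1 (0.186) or resistant replicate 3 (0.0885), and the interferon call without parental replicate 1 (0.197), resistant replicate 1 (0.101) or resistant replicate 3 (0.901). In lists too small to test, the leukocyte gene CD3D fell by 3.31 ± 0.32 with 1 marker higher and 2 lower, and VWF fell by 1.62 ± 0.43 among endothelial markers, also 1 higher and 2 lower.

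Within the Huh7 selection limma called 3614 genes higher and 3917 lower, 959 and 968 of them by 2-fold or more, and the median log2 fold change was -0.19 (-0.13 with median centring). The majority direction rested on the scaling, DESeq2 with its own size factors calling 3615 higher and 3498 lower (50.8% higher). Every list member measured in Huh7 was called both over all genes and adjusted over the list alone, and 32 of 35 lists passed fry. When the direction of list members was set against all genes of the table by a two-sided Fisher exact test, no list passed. The lowest adjusted p was 0.0581, shared by the xenobiotic, TGF-beta, YAP/TAZ, ER chaperone and histone lists.

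**Figure D2:**
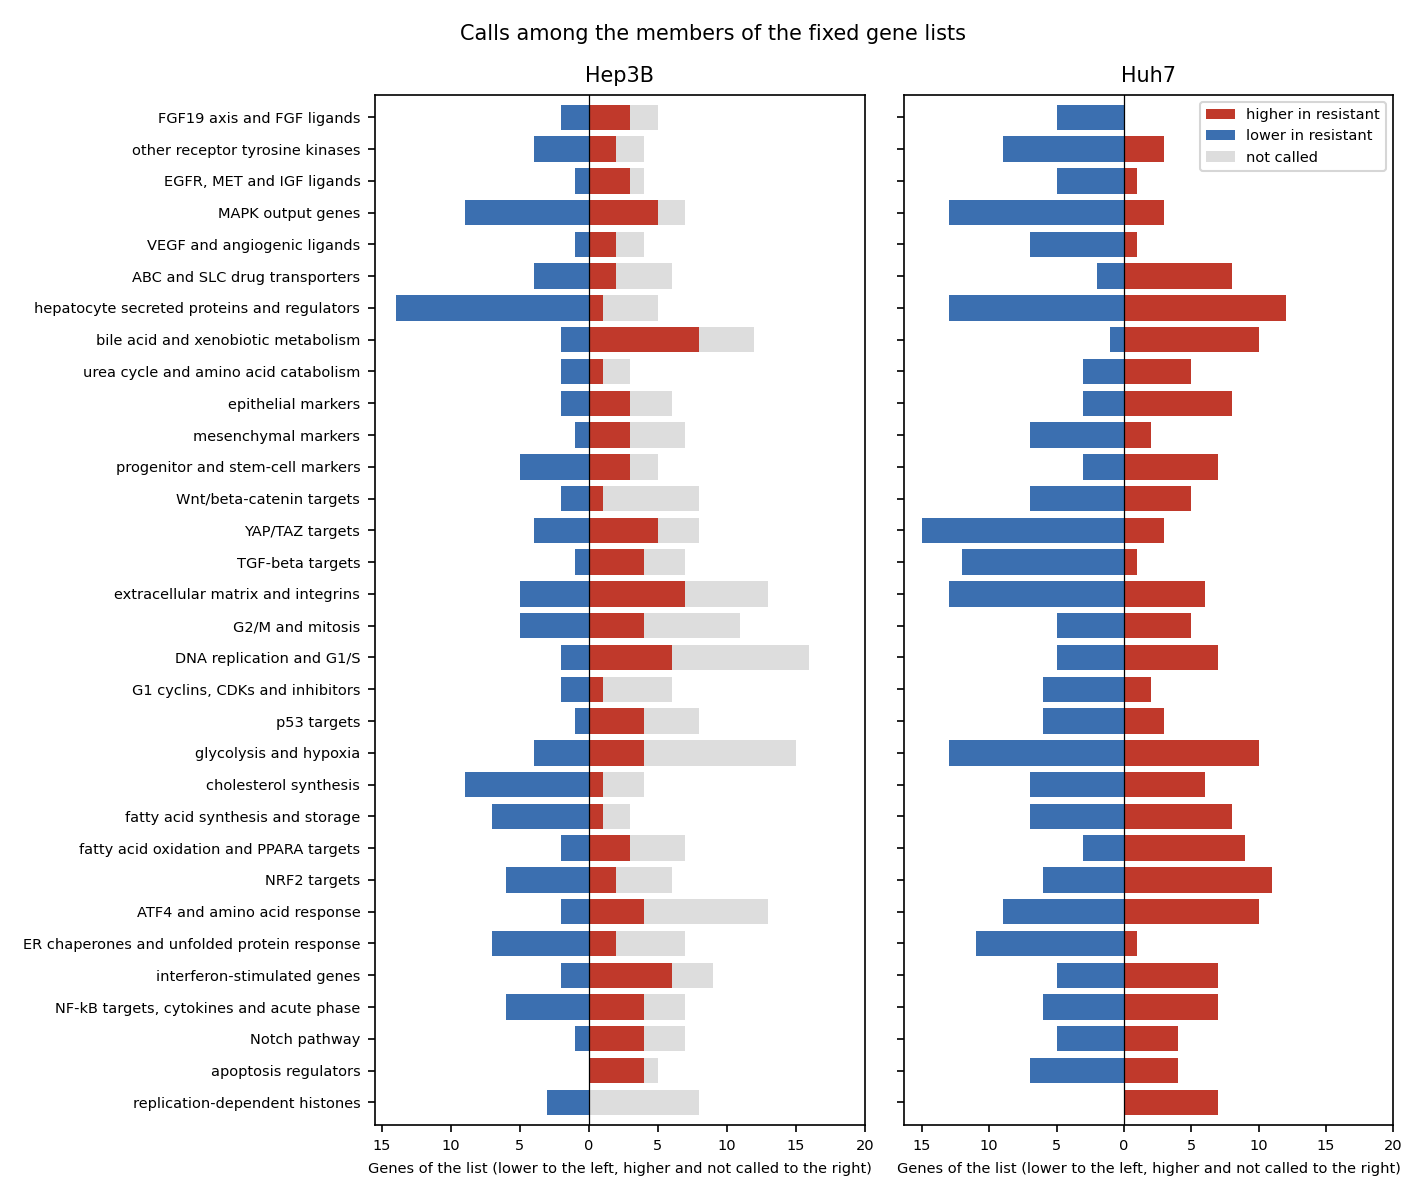
Number of members of each fixed list higher (red, right), lower (blue, left) and not called (grey, right of the red bar) in resistant cells of Hep3B and Huh7, for lists with at least 5 measured members in both lines. Every Huh7 gene comes from a selection of changed genes. Of the secreted liver proteins 14 fell in Hep3B, and of the TGF-beta targets 12 fell in Huh7.

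The comparison between the lines addresses whether resistance came with the same changes in both. Shared changes included a fall of CCND1, FGF19 and KLB and a rise of SULT1E1 and PDGFRA in resistant cells of both lines. The Hep3B rise of PDGFRA is that of 1 of its 5 RefSeq transcripts. Common changes were ranked by the smaller of the absolute changes in both lines. The strongest common rises were those of the succinate receptor gene SUCNR1, with 1 parental read in each line (52.1-fold in Hep3B, counting interval 8.94 to 2096, and 47.1-fold in Huh7, 8.02 to 1903), NYNRIN (log2 3.24 ± 0.15 and 2.55 ± 0.13), GOLGA7B (3.00 ± 0.59 and 3.11 ± 0.44), RAB9B (46.1-fold in Hep3B, 7.87 to 1859, and log2 2.54 ± 0.53 in Huh7) and RAB20 (2.59 ± 0.69 and 2.59 ± 0.41), the Hep3B call of RAB20 being lost without resistant replicate 1 (limma adjusted p = 0.0566). The strongest common falls were those of the cardiac myosin-binding gene MYBPC3 (-3.78 ± 0.30 in Hep3B and 73.3-fold lower in Huh7, 24.8 to 358), the axon guidance receptor ROBO3 (58 parental reads against 2 in Hep3B, with a counting interval of the ratio from 7.66 to 245, and 43 against 1 in Huh7), the prostaglandin D2 receptor PTGDR2 (-2.47 ± 0.30 and -2.89 ± 0.12), GAL3ST3 (-2.57 ± 0.54 and -2.35 ± 0.67) and the inhibin subunit INHBB (-3.88 ± 0.14 and -2.22 ± 0.20). The Huh7 call of GAL3ST3 was lost with limma without trend and with DESeq2's own size factors.

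Other genes went opposite ways. The collagen genes COL1A1 and COL1A2, LOXL2 and PDGFB rose in Hep3B and fell in Huh7, as did IRF8, a transcription factor of myeloid cells (2.67 ± 1.14 to 106 ± 9.92 in Hep3B and 138 ± 16.2 to 4.15 ± 6.31 in Huh7). CXCL5 fell in Hep3B (2292 ± 191 to 345 ± 14.6) and rose in Huh7 (1494 ± 179 to 5422 ± 266). CDX2 fell in Hep3B and rose in Huh7 (637 ± 31.6 to 1148 ± 80.5), and RFX6, an endocrine transcription factor, fell from 69.2 ± 7.16 to 29.3 in Hep3B and rose from 18.2 ± 2.17 to 243 ± 27.5 in Huh7.

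Of 3885 shared genes, 1191 had a more positive change in Huh7 and 1437 a more negative one by the test of the difference, 440 and 689 of them by 2-fold or more. Calls higher in both lines numbered 471 against 512 for independent lists (ratio 0.92, one-sided Fisher exact p = 0.998), and calls lower in both 529 against 550 (0.96, p = 0.940). Higher in Hep3B and lower in Huh7 were 646 against 605 (1.07, exact p = 0.00193), and the reverse 486 against 465 (1.04, p = 0.0695). Every shared gene was called in Huh7, so the opposite counts follow from the same-direction counts. Each opposite test is therefore the other tail of a same-direction test and no separate result. Among genes changed by at least 2-fold in both lines, 3 direction pairs were more frequent than for independent lists: 83 against 31.6 higher in both (ratio 2.63, one-sided Fisher exact p = 2.34e-18), 43 against 23.2 lower in both (1.85, exact p = 3.12e-05) and 111 against 41.4 higher in Hep3B and lower in Huh7 (2.68, exact p = 7.62e-26). The other pair, 22 against 17.7, did not pass (1.24, exact p = 0.168). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.03 and a Spearman rho of -0.03, and 47.8% had the same sign.

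Of 32 lists tested in both lines, 3 passed with tests pointing the same way: secreted liver proteins and ER chaperones down, and bile acid and xenobiotic metabolism up. The bile acid and xenobiotic list did not pass in Hep3B when adjusted over the Hep3B lists alone. Another 3 passed with tests pointing opposite ways, cholesterol synthesis and fatty acid synthesis down in Hep3B and apoptosis regulators up. In Huh7 the members of these 3 lists were divided, 6 higher and 7 lower, 8 higher and 7 lower, and 4 higher and 7 lower, as were those of the secreted liver proteins, so the direction there is that of the fry test alone. With an estimated correlation in Hep3B, 1 list passed in the same direction and 0 in opposite directions. In Huh7, secreted liver proteins did not pass with median centring (adjusted p = 0.937, range over alternatives 4.6e-05 to 0.937), nor cholesterol synthesis with the replicate block (0.0967, range 0.00218 to 0.0967). Apoptosis regulators did not pass there with the replicate block (0.220, the highest over alternatives, the lowest being 0.0032) or without resistant replicate 1 (0.0746). These overlaps lie within genes selected for a change in Huh7, and an entry in Hep3B can cover only 1 transcript of its gene.

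**Figure D3:**
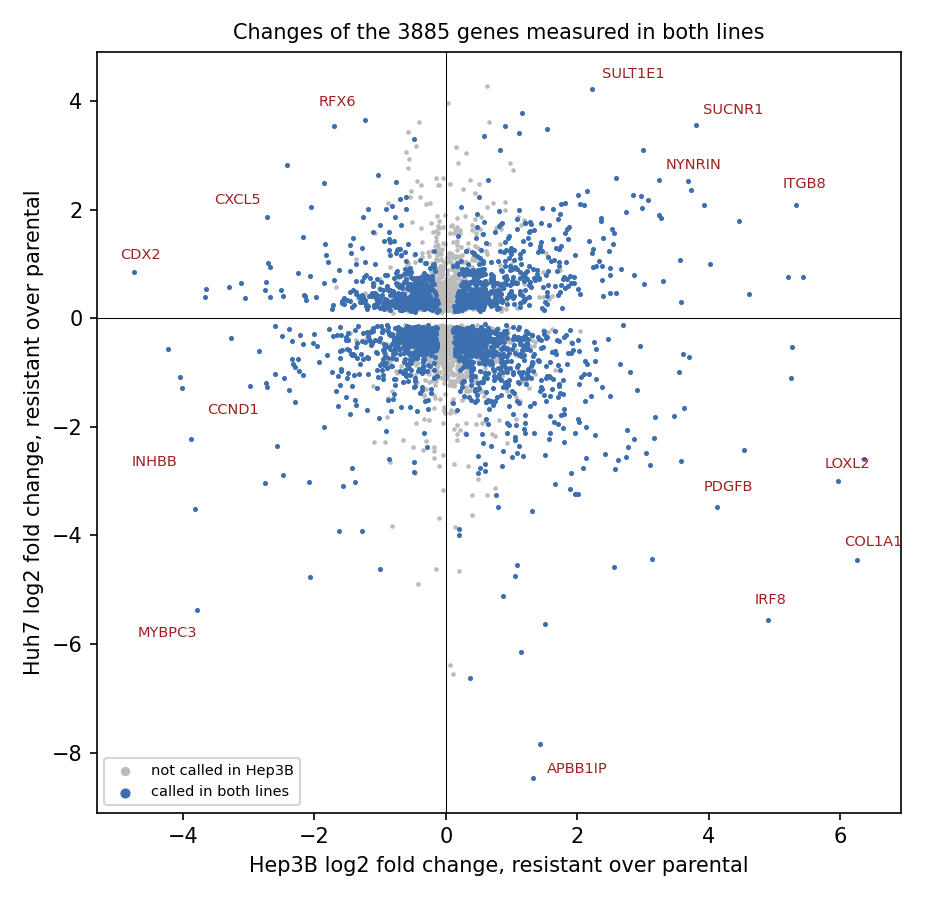
Log2 fold change, resistant over parental, in Hep3B (horizontal) and Huh7 (vertical) for the 3885 genes in both tables, blue where called in both lines and grey where not called in Hep3B. The empty band along the horizontal axis comes from the selection of changed genes in Huh7. Points lie in all 4 combinations of signs, and the Pearson r across genes was -0.03.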

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

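The tests of the unrelated changes of the lines and of fibroblasts were chosen after the result was seen; the counts of other splits and the test for Huh7 cells were planned before.

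Changes that differ between the lines were picked out by the test of the difference itself: 1191 shared genes had a more positive change in Huh7 and 1437 a more negative one. Of 284 named genes 161 were in both tables, and 135 of these passed the test of the difference, 75 with opposite calls. Over all 3885 shared genes 2628 passed. The naming rule picks large changes and large differences, so a high share of named genes passing is built in. The largest differences among opposite calls, Huh7 minus Hep3B on the log2 scale, were those of CDX2 (5.60 ± 0.56), CCNB3 (5.25 ± 0.68), PRODH2 (5.24 ± 0.93), RFX6 (4.89 ± 0.29) and CXCL5 (4.59 ± 0.10), and on the other side COL1A1 (-10.70 ± 0.19), IRF8 (-10.47 ± 0.67), APBB1IP (-9.80 ± 0.38), KIRREL1 (-9.27 ± 0.58) and LOXL2 (-8.97 ± 0.23). Those of CDX2, PRODH2 and APBB1IP rest on groups with 0 to 3 reads and are no bounds. The Hep3B call of CCNB3 was lost under 10 alternatives, leaving out any library but resistant replicate 2 among them, with limma adjusted p from 0.0532 without parental replicate 2 to 0.215 without resistant replicate 3. The Hep3B call of PRODH2 was lost without trend and without parental replicate 3 (limma adjusted p = 0.0819), that of KIRREL1 without resistant replicate 2 (0.0521), and the Huh7 call of CDX2 with all 12 libraries in 1 fit (0.0834). Of the common changes, NYNRIN and INHBB also differed in size by this test. So did MYBPC3, whose resistant Huh7 group has 3 reads, but not with quantile normalization (-1.12, adjusted p of the limma difference 0.0647).

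Splitting the 6 libraries of a line in all 10 ways gives too few splits for a share under 0.05. The real split gave 4317 genes in Hep3B, with 1 of 10 splits as large and 0 in the highest of the others, and 7531 in Huh7, with 1 of 10 as large and 0 in the highest other. With adjustment within the line, the real split gave 5 lists in Hep3B (1 of 10 as large, highest other 3) and 33 in Huh7 (1 of 10, highest other 0). For the difference between lines, the real pair of splits gave 2628 genes and the highest of the others 1634. Of 100 drawn pairs, 1 was as large. This count and the Huh7 counts of genes and lists decide nothing, because the Huh7 genes were selected on the real split.

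The changes of the lines were nearly unrelated across shared genes. Had a transcript-level measure hidden a common response, genes with 1 RefSeq transcript would correlate, but their Pearson r was 0.0169 (95% interval -0.0538 to 0.0940). Genes with a mean of at least 100 scaled reads had an r of -0.0455 (-0.124 to 0.0291), which argues against noise of genes with few reads. Exchanged parental and resistant names in 1 line would turn a common response into a clearly negative r. The r of -0.0267 (-0.0785 to 0.0231) over all shared genes argues against a common response hidden in this way. Without a common response r would be small with or without an exchange, so an exchange as such is not excluded. That the lines reached resistance by different routes, or that each culture drifted, stays open and was not tested.

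The rise of COL1A1 and LOXL2 in resistant Hep3B could come from other cells in the cultures. Fibroblasts stay open: the 3 other measured fibroblast markers went both ways (median -2.1), with COL1A2 at 2.03, PDGFRB at -2.10 and LUM at -2.38, and parental Hep3B already had 203 scaled reads of PDGFRB and 355 of LUM, whose own fall would hide a small share of fibroblasts. Huh7 cells, whose parental level of COL1A1 is high, would have to supply 121% of that level, while 12 other genes high in Huh7 and low in Hep3B gained an upper quartile of 1.59% of their Huh7 level (median 0.410%, highest 9.65%). These levels come from separately normalized tables. This argues against Huh7 cells. A change in the Hep3B cells themselves stays open as well, as a hypothesis.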

How the results depend on the processing

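Tests on edgeR and DESeq2, genes with 1 RefSeq transcript, a mean of at least 100 scaled reads, shared symbols and the direction of list members were chosen after the data were seen. Of the summary results' values under alternatives, 225 planned and 49 added ones were on the same side or within 1.5 times the value reported. The others follow. Counts of genes are lower by construction where fewer genes were tested or a fold was required. The joint fit held only shared symbols, but its counts also differed from those of the main fit over shared symbols. For that difference, the overlap ratios and the lists, the cause was not tested. Hep3B calls were 1579 higher at a mean of at least 100, 1481 higher and 1155 lower over genes with 1 transcript, 1199 and 1078 with all 12 libraries in 1 fit, 1117 and 1015 over shared symbols, and 931 and 411 at 2-fold or more. Huh7 calls were 1472 and 1759 in the joint fit, 1781 and 2104 over shared symbols, and 959 and 968 at 2-fold or more. Genes whose change differs were 664 and 811 over genes with 1 transcript and 440 and 689 at 2-fold or more. The overlap ratio was 2.63 for higher in both and 1.85 for lower in both at 2-fold or more. At 2-fold the ratio for higher in Hep3B and lower in Huh7 was 2.68, so the excess was not confined to shared directions. For lower in Hep3B and higher in Huh7 it was 1.06 with quantile normalization, 1.06 at a mean of at least 100, 1.14 in the joint fit and from 1.01 to 1.05 with 1 library left out, passing without Huh7 resistant replicate 2 (1.05). Hep3B lists passing were 1 with an estimated correlation, 26 with fry and 4 over genes with 1 transcript, and Huh7 lists passing were 0 by the direction of members. Lists passing in both lines were 1 in the same and 0 in opposite directions with an estimated correlation, 11 and 14 with fry, and 1 in opposite directions over genes with 1 transcript. With 1 library left out, those in opposite directions ran from 2 (without Huh7 resistant replicate 1) to 5 (without Hep3B parental replicate 2 or Hep3B resistant replicate 3).

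With 1 library left out, Hep3B calls ran from 2038 to 2279 higher and from 1695 to 1847 lower, Huh7 calls from 3499 to 3601 and from 3799 to 3882. With the replicate number as a block, Hep3B gave 2703 and 2178; deviations of equal numbers correlated at 0.113, 0.262 and 0.134 in Hep3B over genes with a mean of at least 31 scaled reads (0.0371, 0.0891 and 0.0558 over all; best match with the own number in 6 of 6 both ways) and at 0.0395, -0.0262 and 0.139 in Huh7 (2 of 6), so shared days are not excluded in Hep3B. With the block, the Hep3B TGF-beta and NRF2 lists and the Huh7 Notch list passed, and the Huh7 cholesterol, ATF4 and apoptosis lists did not. Of 7040 values of named genes under alternatives 6883 kept direction and call, 157 lost the call and 0 reversed; 38 of 360 results were touched. Count tests as the reported test and camera in Huh7 were not run, since the units differed and the Huh7 table is a selection. Of simulated 1.5-fold changes 58.2% were found in Hep3B; how far depth limits this was not tested by read level.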

Other observations

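The tests of random gene orders and of adjacent genes were chosen after the result was seen; the test of GC content, length and level was planned before. The chromosomes and the genes named only here were chosen after their values were seen.

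Several genes fell to 0 reads in resistant Huh7: beside APBB1IP, DPPA4, CHM and APOOL, these were INPP5D (at least 54.2-fold lower), LPL (at least 33.8-fold) and SLFN11, a gene that sensitizes cells to DNA damage (at least 32.9-fold). DGKI appeared from 0 reads (at least 34.7-fold higher). RTL1 and DIO3, neighbours in an imprinted cluster, both rose in Hep3B, while RTL1 went from 17 reads to 0 in Huh7. CCND1 and FGF19 lie near each other. Near them SHANK2 (-1.52), FADD (-0.64) and TPCN2 (-0.57) also fell in Hep3B, while CPT1A rose there (1.53). In Huh7 FADD (-0.46) and SHANK2 (-0.39) fell as well.

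Genes near each other changed together. Ranked log2 fold changes 20 places apart correlated at 0.0901 in Hep3B and 0.138 in Huh7, where the highest of 1000 random orders gave 0.0329 and 0.0315, which argues against chance order. Adjacent genes correlated at 0.183 and 0.299, but genes 20 places apart do not adjoin, so reads shared by adjacent genes are not the whole cause. With deciles of GC content, transcript length and level removed the correlation was 0.0739 and 0.0895, which argues against these as the whole cause. A candidate explanation is a gain or loss of chromosome segments, or a regional change of chromatin; neither was tested.

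Whole chromosomes leaned one way. On the one carrying ATP5F1A and SMAD4, 124 of 138 Huh7 genes were higher (89.9%, median 0.64), and on the one carrying GPC3, CHM and APOOL 57 of 235 were (24.3%, median -0.42). On the one carrying FTL 82 of 496 were higher (16.5%, median -0.55, and -0.24 with deciles of GC content, length and level removed), and on the one carrying ENO1 190 of 730 (26.0%, median -0.37). In Hep3B, 107 of 427 genes on the one carrying TUBA1B and HSP90B1 were higher (25.1%, median -0.34), 149 of 430 on the one carrying FTH1 (34.7%), 93 of 261 on the one carrying THBS1 (35.6%) and 26 of 80 on the one carrying HMGN1 (32.5%). Random orders gave shares from 36.2% to 73.8% in Hep3B and from 31.3% to 70.2% in Huh7.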
